A study of Rattus norvegicus with 6 samples.

How the data were processed

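Polyadenylated mRNA from rat common carotid arteries was sequenced in 6 libraries. Per the labels, a clot had been produced with ferric chloride, an oxidant salt that injures the vessel wall, and the vessel had been reopened with sonodynamic therapy, in which ultrasound excites a sensitizer, together with a treatment the submitters call physical-explosion therapy. The groups were 1 normal artery (control), 3 arteries collected 1 day after recanalization and 2 collected 7 days after it.

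The deposited read counts, made by the authors, hold 24005 gene symbols, of which 5156 had 0 counts in every library. The deposited FPKM values were also made by the authors. The count divided by the FPKM and by the library total gave 1 length per gene in all 6 libraries, with a relative spread of at most 2.2e-14 over 14607 genes, so the FPKM values are the counts scaled by gene length and library total. Fastp 0.18.0, Bowtie2 2.2.8, HISAT2 and StringTie 1.3.1 are named in the submitters' processing notes. The role of each aligner, the genome build and the annotation are not given in the sources used here. Of the symbols, 17871 matched a gene symbol of the GRCr8 reference annotation and 2138 matched only a synonym there, and no coordinates were used.

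Total counts per library were 30078022 to 47240013, and 3 counts, the floor per library used here for a gene at 0, correspond to 0.0598 to 0.0974 CPM, the count scaled by the normalized library total. Intervals and floors cover counting error only. Genes passing the filterByExpr function of edgeR by group (15860) were normalized by the trimmed mean of M-values. They were tested with the edgeR 4.0.16 quasi-likelihood test with robust dispersions in R 4.3.3, in 1 fit with 3 group means. The fit leaves 3 residual degrees of freedom, all from the treated groups, and the control was assumed to vary like them. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use the same normalization factors. Folds are log2 fold changes with a standard error (SE) from the fit, and SD values are over the libraries of a group.

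Gene lists and cell type markers (29 lists with enough tested members) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Members of each list were also adjusted over the list alone. For lists with members at 0 in every library of a group, the median is also given with those members set to the floor per library. The comparisons, lists, tests, threshold and named genes were chosen before the data were examined. The rule named, in each comparison, up to 8 genes per direction past the threshold with an average log2 CPM of at least 3 and no overlap between groups, the 3 members of each described list with the smallest unadjusted p, and a fixed set (Acta2, Pecam1, Vwf, Il1b, Il6, Ccl2, Cd68, Spp1, Col1a1, Mmp9, Hmox1, Mki67 and Plat among them). Some genes that the rule names are not reported here. No gene met its first part. Other genes are named as chosen after their values were seen.

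The pipeline was tested on simulated data with the same group sizes and gene-wise dispersions, and 100 genes, drawn from those with a mean of at least 8 CPM, changed at each of 4-fold and 16-fold. For day 7 against day 1, edgeR called 39 of the 100 genes at 4-fold and 93 at 16-fold, and 10 unchanged genes, with 15462 genes in the step. For day 1 against the control it called 13 and 75, with 13 unchanged genes (15443 genes in the step), and for day 7 against the control 9 and 79, with 6 unchanged genes (15481 genes in the step). DESeq2 on the same simulated counts called 72 and 98 for day 7 against day 1, with 110 unchanged genes. It called 56 and 98 with 132 unchanged genes for day 1 against the control, and 53 and 96 with 114 unchanged genes for day 7 against the control. Simulated libraries were drawn independently, so none stood apart from its group across many genes as day 1 replicate 1 does in the data. For day 1 against the control, leaving that library out lowered the simulated edgeR calls from 13 and 75 to 6 and 69. In the data it raised the calls from 0 to 885. The simulated rates may therefore not hold for these data.

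The alternatives tried were median-of-ratios and upper-quartile factors, no count filter or a CPM of at least 1 in 2 libraries, limma-voom, the DESeq2 1.42.0 Wald test, limma-trend on log2 FPKM with 1 or 0.1 added, an added 2-fold threshold, leaving out haemoglobin and mitochondrially encoded genes, leaving out each treated library in turn, the 5 treated libraries alone, and replicate numbers as a block. Lists were also tested with an estimated correlation and with fry, both on all 6 libraries. With another normalization or a library left out, list p-values used the preset correlation alone. Members of some lists varied together (estimated correlation 0.974 for macrophage and 0.98 for erythroid markers), so these p-values may be far too small. DESeq2 without day 1 replicate 1 was added after the data had been seen. Lists that passed in no comparison are not all described, and 1 further marker list with 1 tested member was not tested. Read-level data were not used here.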

Results

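The data describe how the rat carotid artery differed in its messenger RNA after a ferric chloride clot had been cleared, at 1 day (3 libraries) and 7 days (2 libraries), from a normal carotid artery (1 library). Library totals were 32013817 counts for the control, 36076387, 31188546 and 30078022 for day 1 replicates 1 to 3, and 47240013 and 31268481 for day 7 replicates 1 and 2. Between 16036 and 17195 genes were detected per library. The control has no replicate, so its own spread is unknown. No group had the injury or the treatment alone. Against a normal artery, effects of ferric chloride, the clot, sonodynamic therapy and physical-explosion therapy therefore cannot be told apart. The p-values measure only the spread between these samples, since the labels do not state whether the libraries come from separate animals.

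Day 1 replicate 1 stood apart from the other day 1 libraries, and whether its label is right was not settled. Across genes, which are not independent replicates, its log2 CPM had a Pearson r of 0.948 with the control, 0.883 with day 1 replicate 2 and 0.919 with replicate 3, whereas replicates 2 and 3 had 0.958 with each other and the day 7 pair 0.953. The first principal component, with 54.6% of the variance, placed the control at -118 and day 1 replicate 1 at -113, and the other 4 libraries between 32.3 and 73.8. Mitochondrially encoded transcripts took 3.42% of the counts in the control (Wilson 95% interval 3.41 to 3.43%), 3.84% (3.84 to 3.85%) in day 1 replicate 1, 5.73% (5.72 to 5.73%) and 7.20% (7.19 to 7.21%) in day 1 replicates 2 and 3, and 4.01% (4.01 to 4.02%) and 3.58% (3.57 to 3.59%) at day 7.

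The first comparison asked which transcripts of the artery differed 1 day after recanalization. The 7 genes of inflammation and cell division named next had a higher CPM in each day 1 library than in the control. Vcam1, which holds leukocytes on activated endothelium, stood at 507 ± 79.0 CPM (mean ± SD, n = 3) against 86.6 CPM in the control, and Ptgs2, the inducible prostaglandin synthase, at 182 ± 39.4 CPM against 18.3. Il6, a cytokine of acute inflammation, had 61.1, 95.6 and 36.9 CPM in the 3 libraries against 0.0649 in the control. Ccl2, which attracts monocytes, had 66.5, 404 and 136 CPM against 0.130, and Il1b, an early cytokine of myeloid cells, 3.62, 166 and 97.3 CPM against 0.455. Mki67, a marker of dividing cells, was at 59.5 ± 2.92 CPM (n = 3) against 6.75, and the mitotic cyclin Ccnb2 at 7.48 ± 0.970 CPM (n = 3) against 0.357.

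All 16 tested genes of the inflammatory list were higher at day 1, with a median log2 fold change of 8.60, or 7.13 with its 4 members that were at 0 in a group set to the floor (camera adjusted p = 3.44e-13, adjusted p = 0.364 with an estimated correlation). Of these, 8 were higher when adjusted over the list alone. Selp, an adhesion molecule of the list chosen after its values were seen, had 3.71 CPM in day 1 replicate 1 against 5.62 in the control. All 18 cell cycle genes were higher, by a median log2 fold change of 2.55 (camera adjusted p = 7.29e-20, adjusted p = 0.364 with an estimated correlation), 15 of them when adjusted over the list alone. In day 1 replicate 1 the inflammatory median over the control was 2.55 on the log2 scale, against 8.17 and 7.41 in replicates 2 and 3, while the cell cycle median was 2.94 against 2.41 and 2.37. The 15 immediate early genes, which are induced within minutes of a stimulus, were all higher by a median of 2.43 (camera adjusted p = 7.61e-08, adjusted p = 0.507 with an estimated correlation), and 0 were called when adjusted over the list alone. Among them Junb had 622 ± 217 CPM (n = 3) against 75.3 in the control.

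**Figure D1:**
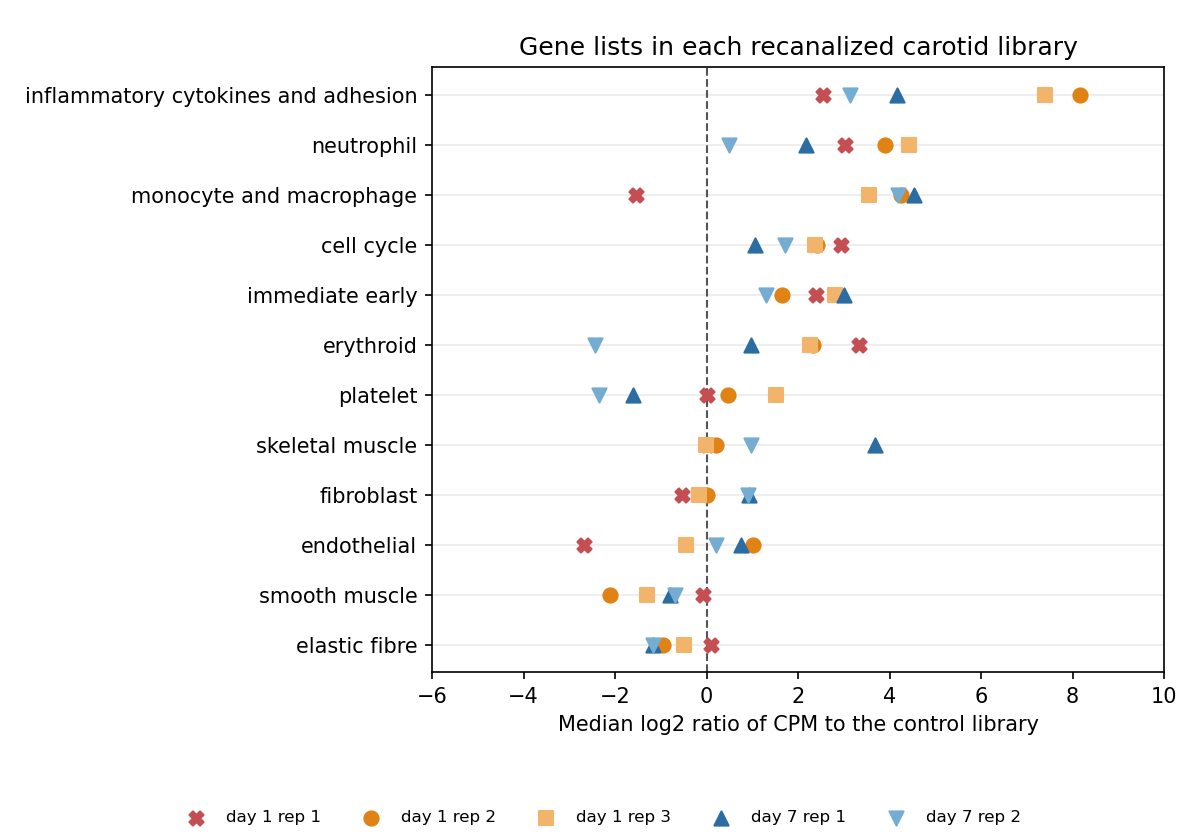
Median log2 ratio of CPM to the control library for 12 marker and gene lists, with 1 point per treated library and the control at the dashed line. For the monocyte and macrophage list, day 1 replicate 1 lies at -1.55 and the other 4 libraries lie between 3.55 and 4.53.

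Leukocyte transcripts at day 1 depended on the library. Cd68, a lysosomal protein of macrophages, had 1.47, 262 and 142 CPM in day 1 replicates 1 to 3 against 1.10 in the control, and Lyz2, the lysozyme of myeloid cells, 27.5, 4731 and 1902 CPM against 13.1. The median of the 13 monocyte and macrophage markers over the control was -1.55 in day 1 replicate 1, 4.25 in replicate 2 and 3.55 in replicate 3, and the list did not pass (camera adjusted p = 0.0956). With that library left out the list passed with a median of 3.99 (camera adjusted p = 5.00e-11, over 7 other normalizations and left-out libraries 5.00e-11 to 0.538), and edgeR called 9 of its members higher. Neutrophil markers were higher in all 3 libraries, with Csf3r, the receptor for granulocyte colony-stimulating factor, at 4.39, 23.5 and 25.8 CPM against 0.325. All 10 tested neutrophil markers were higher, by a median log2 fold change of 5.79, or 3.99 with 4 members at the floor (camera adjusted p = 1.57e-06, adjusted p = 0.364 with an estimated correlation), and 0 were called when adjusted over the list alone. The 10 tested T and NK cell markers were all higher, by a median of 7.16, or 2.98 with 7 members at the floor (camera adjusted p = 4.63e-05, adjusted p = 0.507 with an estimated correlation), and 1 was called when adjusted over the list alone. Genes of lipid-laden phagocytes such as Spp1, the matricellular protein osteopontin (1127, 6315 and 6387 CPM against 484), had a median of 3.0 with 12 of 13 members higher (camera adjusted p = 0.000476, adjusted p = 0.507 with an estimated correlation). Their median was 0.26 in day 1 replicate 1 and 3.70 and 3.07 in replicates 2 and 3. Mmp9, a gelatinase carried by neutrophils and macrophages, had 0.801, 86.9 and 39.6 CPM against 0.260.

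Contractile genes of smooth muscle were lower at day 1 in replicates 2 and 3. Acta2, smooth muscle actin, had 12640, 2613 and 2909 CPM in replicates 1 to 3 against 9324 in the control, and Lmod1, an actin nucleator of smooth muscle, 558, 161 and 327 CPM against 973. All 15 smooth muscle markers had a negative fold change, with a median of -0.69 (camera adjusted p = 0.000204, adjusted p = 0.507 with an estimated correlation), and 0 were called when adjusted over the list alone. By library the median was -0.08, -2.11 and -1.29. The list's median was -1.67 without replicate 1 and -0.44 without replicate 2. The endothelial list did not pass (camera adjusted p = 0.377), and its median of 0.52 was positive although the test pointed downward. Vwf, the von Willebrand factor of endothelial cells and platelets, had 65.1, 262 and 72.8 CPM against 721, and Pecam1, an endothelial junction protein, 11.8, 115 and 23.7 CPM against 169. By library the endothelial median was -2.67, 1.01 and -0.44, and without replicate 2 the list passed downward with a median of -1.07 (camera adjusted p = 0.000788, over the alternatives 0.000788 to 0.766).

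Genes that regulate clotting, oxidants and matrix were also higher at day 1. Plat, tissue plasminogen activator, stood at 341 ± 87.6 CPM (n = 3) against 117 in the control. Of the 15 coagulation and fibrinolysis genes, 13 were higher, with a median of 1.05 (camera adjusted p = 0.00198, adjusted p = 0.507 with an estimated correlation) that was 0.68 without day 1 replicate 2, and 5 were called when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, was at 482 ± 92.9 CPM (n = 3) against 91.1, and Hmox1, which degrades haem, at 76.5, 376 and 149 CPM against 3.70. Of the 13 oxidative stress genes, 12 were higher by a median of 2.04 (camera adjusted p = 1.77e-05, adjusted p = 0.507 with an estimated correlation), 2 of them when adjusted over the list alone. Timp1, a metalloproteinase inhibitor, was at 207 ± 69.5 CPM (n = 3) against 40.4, and Thbs1, thrombospondin 1, at 600, 3440 and 1318 CPM against 5.65. The fibrillar matrix list that holds both had a median of 0.70 with 10 of 15 members higher (camera adjusted p = 0.0219, adjusted p = 0.507 with an estimated correlation), 2 of them when adjusted over the list alone. It did not pass without day 1 replicate 1 (camera adjusted p = 0.0537) and its median was 0.37 without replicate 2. Col1a1, the main fibrillar collagen, was at 10380 ± 1854 CPM (n = 3) against 13530.

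Blood and nerve transcripts differed as well. Haemoglobin genes summed to 6975, 3992 and 3384 CPM in day 1 replicates 1 to 3 against 791 in the control. All 10 erythroid markers were higher by a median of 2.76 (camera adjusted p = 0.000140, adjusted p = 0.507 with an estimated correlation), 0 of them when adjusted over the list alone, and the platelet list did not pass (camera adjusted p = 0.165). Sox10, a transcription factor of Schwann cells, had 0.422 CPM in the control and 0, 0.0617 and 0 CPM at day 1. Of 9 Schwann cell and nerve markers, 7 were lower, with a median of -0.17 and a mean of -2.36 (camera adjusted p = 0.00969, adjusted p = 0.364 with an estimated correlation), and 1 was called when adjusted over the list alone. By fry this list passed (fry adjusted p = 0.0152), as did the cell cycle list (0.0436). This list did not pass without day 1 replicate 1 (camera adjusted p = 0.0854) or day 7 replicate 2 (camera adjusted p = 0.0674), and its median was -0.38 without day 1 replicate 3. Higher by camera were also the matrix proteases (median 5.79, or 2.79 with 4 members at the floor, adjusted p = 0.00289), heat shock genes (0.46, adjusted p = 0.00854), smooth muscle modulation genes (0.78, adjusted p = 0.00854), hypoxia and glycolysis genes (0.62, adjusted p = 0.0110) and iron handling genes (0.72, adjusted p = 0.0297). The matrix protease median by library was 0.64, 4.77 and 3.32 in replicates 1 to 3. These lists had an adjusted p = 0.364 with an estimated correlation for the modulation genes and an adjusted p = 0.507 with an estimated correlation for the other 4 lists. Heat shock (camera adjusted p = 0.142) and hypoxia genes (0.0566) did not pass without day 1 replicate 1, and iron handling genes did not without day 1 replicate 2 (0.0502) or 3 (0.0981). Besides the macrophage list, 2 lists passed only without day 1 replicate 1, interferon response genes as higher (median 1.51, camera adjusted p = 0.00686, 2 called by edgeR) and elastic fibre genes as lower (median -0.73, camera adjusted p = 0.0375).

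edgeR called 0 of 15860 genes, limma-voom 0 and DESeq2 815 (706 higher, 109 lower), a test that called 132 unchanged genes in the simulation. At an unadjusted p under 0.05 edgeR had 1373 genes (972 higher, 401 lower), where 793 were to be expected by chance. When day 1 replicate 1 was left out edgeR called 885 genes (763 higher, 122 lower), among them 11 inflammatory and 11 cell cycle genes, all higher. The smallest adjusted p belonged to Fam111a, a protease gene of cell replication, chosen after its values were seen, at 95.6 ± 10.4 CPM (n = 3) against 1.36 in the control (edgeR adjusted p = 0.136, over 15 alternatives 1.49e-52 with DESeq2 to 0.726). The control lay outside the range of all 3 day 1 libraries for 8680 genes (54.7%, with 50% by chance).

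**Figure D2:**
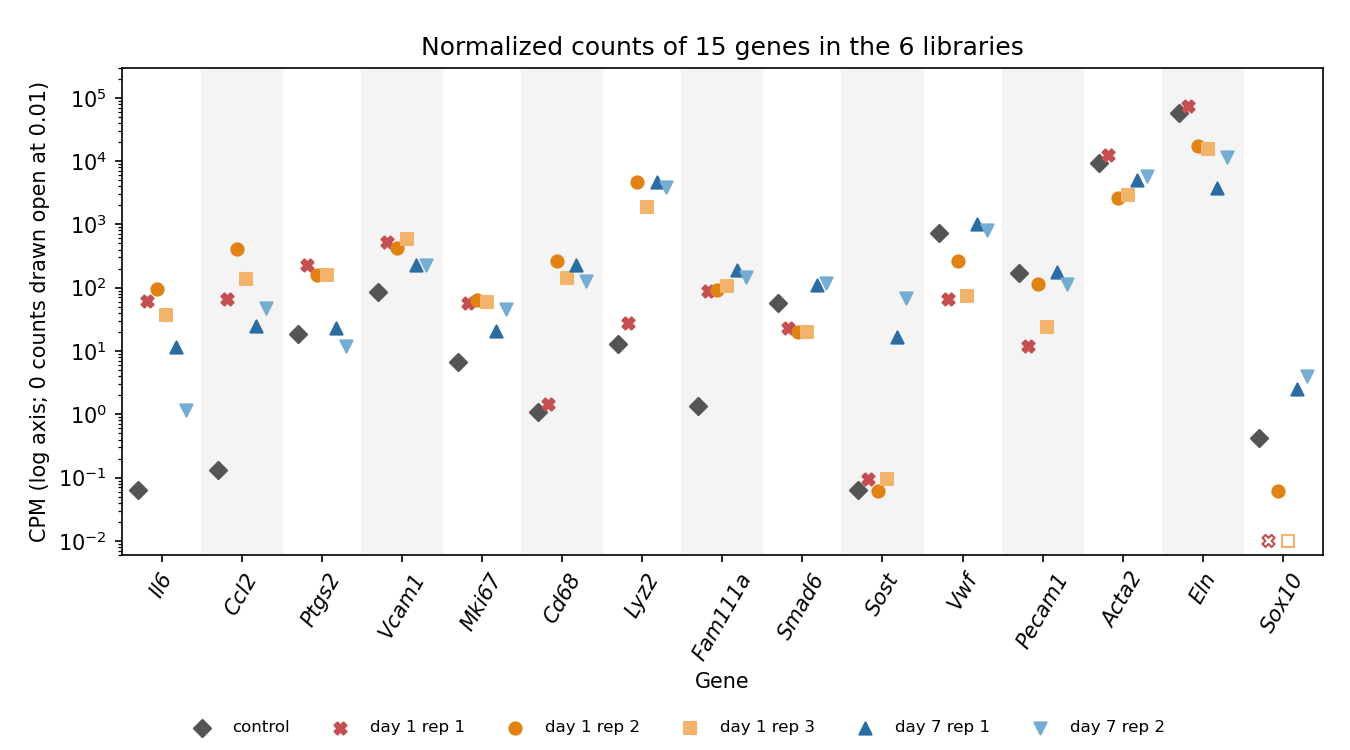
CPM of 15 genes in the 6 libraries on a log axis, with 1 point per library and open points at the bottom for 0 counts, and with Fam111a, Smad6 and Sost chosen after their values were seen. Day 1 replicate 1 lies at 1.47 CPM for Cd68, next to the control at 1.10, but at 227 CPM for Ptgs2, against 18.3 in the control.

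The second comparison asked what distinguished the artery from normal at day 7. Macrophage genes were abundant in both libraries. Lyz2 stood at 4275 ± 496 CPM (mean ± SD, n = 2) against 13.1 in the control, Cd68 at 227 and 128 CPM against 1.10, the complement component C1qc at 187 and 98.5 CPM against 7.79, and Apoe, a lipid carrier secreted by macrophages, at 5601 ± 1240 CPM (n = 2) against 33.2. All 13 monocyte and macrophage markers were higher by a median log2 fold change of 4.49 (camera adjusted p = 0.000206, adjusted p = 0.635 with an estimated correlation), and 0 were called when adjusted over the list alone. With day 1 replicate 1, which enters the pooled spread, left out, edgeR called 9 of them. Spp1 had 3294 and 3742 CPM against 484, Hmox1 310 and 205 CPM against 3.70 and Mmp9 65.3 and 5.32 CPM against 0.260. The lipid-laden phagocyte genes had a median of 2.86 with 12 of 13 higher (camera adjusted p = 7.15e-05, adjusted p = 0.635 with an estimated correlation). The 10 T and NK cell markers were all higher by a median of 8.27, or 3.73 with 7 members at the floor (camera adjusted p = 5.34e-06, adjusted p = 0.635 with an estimated correlation), 6 of them when adjusted over the list alone.

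Inflammatory and cell division genes were still above the normal artery at day 7. Ccl2 had 24.8 and 47.6 CPM against 0.130 in the control, Vcam1 228 ± 2.29 CPM (n = 2) against 86.6, and Mki67 33.3 ± 17.4 CPM (n = 2) against 6.75. Il6 had 11.4 and 1.15 CPM against 0.0649, and Il1b 21.5 and 8.23 CPM against 0.455. All 18 cell cycle genes were higher by a median of 1.5 (camera adjusted p = 7.99e-09, adjusted p = 0.635 with an estimated correlation), 9 of them when adjusted over the list alone. Of the 16 inflammatory genes, 14 were higher by a median of 4.32, or 4.38 with 5 members at the floor (camera adjusted p = 4.43e-05, adjusted p = 0.635 with an estimated correlation), and 0 were called when adjusted over the list alone. All 15 immediate early genes were higher by a median of 2.56 (camera adjusted p = 3.43e-06, adjusted p = 0.635 with an estimated correlation), 2 of them when adjusted over the list alone, and the median was 1.31 without day 7 replicate 1. Sox9, a transcription factor of cartilage and of modulated smooth muscle, was at 9.05 ± 4.51 CPM (n = 2) against 0.195. The smooth muscle modulation list had a median of 1.06 with 9 of 11 higher (camera adjusted p = 0.0124, adjusted p = 0.635 with an estimated correlation). Mmp2, a gelatinase, was at 2232 ± 77.7 CPM (n = 2) against 1135, and the matrix proteases had a median of 2.85, or 2.56 with 4 members at the floor, with 9 of 11 higher (camera adjusted p = 0.0133, adjusted p = 0.635 with an estimated correlation). Heat shock genes had a median of 0.70 with 10 of 11 higher (camera adjusted p = 0.0136, adjusted p = 0.635 with an estimated correlation).

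Elastic fibre, contractile and platelet transcripts were lower at day 7. Eln, which encodes the elastin of the arterial media, had 3752 and 11410 CPM against 56510 in the control, and Mfap2, a microfibril protein, 21.4 ± 4.51 CPM (n = 2) against 74.5. Of 10 elastic fibre genes 7 were lower, with a median of -1.18 (camera adjusted p = 0.0450, adjusted p = 0.635 with an estimated correlation). The list did not pass without day 1 replicate 2 (camera adjusted p = 0.0586) or 3 (0.0633), nor without day 7 replicate 1 (0.101) or 2 (0.0540), and ranged from 0.0355 to 0.101 over 7 alternatives. Of 15 smooth muscle markers 12 were lower by a median of -0.80 (camera adjusted p = 0.0499, adjusted p = 0.725 with an estimated correlation). That list did not pass without day 1 replicate 3 (0.0831), day 7 replicate 1 (0.193) or day 7 replicate 2 (0.0540), nor with median-of-ratios (0.0544) or upper-quartile factors (0.0509), and ranged from 0.00985 to 0.193. Acta2 had 4943 and 5758 CPM against 9324, and the 2 endothelial genes of the fixed set were near the control, Vwf at 1005 and 807 CPM against 721 and Pecam1 at 174 and 115 CPM against 169. The endothelial list as a whole had a median of 0.48 with 11 of 14 higher and did not pass (camera adjusted p = 0.210). Platelet markers were lower in 10 of 11 cases by a median of -2.07 (camera adjusted p = 5.34e-06, adjusted p = 0.635 with an estimated correlation), 3 of them when adjusted over the list alone. Clec1b, a platelet receptor that binds podoplanin, was at 1.66 ± 0.452 CPM (n = 2) against 12.1.

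In 4 further lists the call at day 7 was close to the threshold or was lost without day 7 replicate 1. Oxidative stress genes had a median of 1.14 (camera adjusted p = 0.0154, adjusted p = 0.635 with an estimated correlation), and 0.69 without day 7 replicate 1 (camera adjusted p = 0.252). Skeletal muscle genes had a median of 3.48, or 3.0 with 2 members at the floor (camera adjusted p = 0.0401, adjusted p = 0.682 with an estimated correlation). In the absence of day 7 replicate 1 their median was 1.23 (camera adjusted p = 0.441), and they did not pass without day 1 replicate 1 (0.118) or 2 (0.0526). Coagulation and fibrinolysis genes had a median of 0.55 (camera adjusted p = 0.0450, adjusted p = 0.635 with an estimated correlation) and did not pass without day 7 replicate 1 (median 0.49). Plat had 147 and 196 CPM against 117. Fibroblast genes had a median of 0.79 (camera adjusted p = 0.0478, adjusted p = 0.635 with an estimated correlation). They did not pass without day 7 replicate 1, although their median was then 0.92. Nor did they pass without day 1 replicate 3 (camera adjusted p = 0.0568) or with upper-quartile factors (0.0509). Without day 7 replicate 1 the median was 0.90 for fibrillar matrix genes and -2.72 for erythroid markers. Without day 7 replicate 2 it was 3.12 for neutrophil markers and 0.64 for hypoxia and glycolysis genes. Each of these medians sets 1 day 7 library against 1 control library. Dcn, the collagen-binding proteoglycan decorin, was at 1205 ± 295 CPM (n = 2) against 527 in the control, and Postn, the matricellular protein periostin, at 1628 and 3597 CPM against 476. Col1a1 had 7383 and 14390 CPM against 13530.

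For day 7 against the control edgeR called 0 of 15860 genes, limma-voom 0 and DESeq2 790 (618 higher, 172 lower), with 114 unchanged genes called by DESeq2 in the simulation. edgeR had 1601 genes at an unadjusted p under 0.05 (971 higher, 630 lower), where 793 were to be expected by chance. After leaving out day 1 replicate 1 edgeR called 693 genes (602 higher, 91 lower). Chosen after their values were seen, Fam111a was at 169 ± 29.3 CPM (n = 2) against 1.36 (edgeR adjusted p = 0.0892), the chemokine Cxcl12 at 169 and 188 CPM against 32.5, and Smoc2, a matricellular protein, at 239 ± 29.7 CPM (n = 2) against 21.7 (edgeR adjusted p = 0.477 for both). The edgeR adjusted p without day 1 replicate 1 was 0.00586 for Fam111a, 0.0111 for Cxcl12 and 0.00799 for Smoc2, and over 15 alternatives it reached 0.628 for Fam111a and 0.765 for Cxcl12 and Smoc2. The control lay outside the range of both day 7 libraries for 12535 genes (79.0%, with 66.7% by chance).

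The third comparison, between the 2 time points, asked what differed between 1 day and 7 days after reopening, and was the only comparison with replicates on both sides. Markers of neutrophils, platelets and red cells were lower at day 7 than at day 1. By list median, inflammatory genes were lower at day 7 than in day 1 replicates 2 and 3, but not than in replicate 1. Ptgs2 was at 17.3 ± 7.61 CPM (n = 2) at day 7 against 182 ± 39.4 CPM (n = 3) at day 1, and Il6 at 11.4 and 1.15 CPM against 61.1, 95.6 and 36.9. Haemoglobin genes summed to 1715 and 151 CPM at day 7 against 6975, 3992 and 3384 at day 1. Vwf had the opposite course, with 906 ± 140 CPM (n = 2) at day 7 against 133 ± 111 CPM (n = 3) at day 1, and so had Smad6, an inhibitor of bone morphogenetic protein (BMP) signalling that was chosen after its values were seen, with 114 ± 5.28 against 21.0 ± 1.79 CPM.

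All 16 inflammatory genes had a negative fold change between the groups, with a median log2 fold change of -2.53 (camera adjusted p = 2.74e-05, adjusted p = 0.644 with an estimated correlation). Of these, 2 were called when adjusted over the list alone, 7 had no overlap between the groups, and the median was -1.62 without day 1 replicate 2. By library the inflammatory median over the control was 2.55, 8.17 and 7.41 at day 1 and 4.17 and 3.15 at day 7. Day 1 replicate 1 thus lay below both day 7 libraries. All 10 neutrophil markers were lower, with a median of -2.51, or -2.12 with 1 member at the floor (camera adjusted p = 0.000178, adjusted p = 0.547 with an estimated correlation), 1 of them when adjusted over the list alone. All 11 platelet markers were lower by a median of -3.01 (camera adjusted p = 1.81e-10, adjusted p = 0.547 with an estimated correlation), 9 of them when adjusted over the list alone. Gp9, a subunit of the platelet receptor for von Willebrand factor, was at 0.339 and 0.152 CPM at day 7 against 3.78, 4.38 and 9.63 at day 1. All 10 erythroid markers were lower by a median of -2.94 (camera adjusted p = 6.76e-09, adjusted p = 0.547 with an estimated correlation), 1 of them when adjusted over the list alone, and the median was -5.60 without day 7 replicate 1. All 18 cell cycle genes were lower by a median of -0.93 (camera adjusted p = 6.76e-09, adjusted p = 0.547 with an estimated correlation), and 0 were called when adjusted over the list alone.

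Fibroblast and skeletal muscle markers had a higher list median in both day 7 libraries than in each day 1 library. Macrophage, endothelial and adipocyte markers were higher at day 7 by group, but the libraries overlapped. Over the control, day 1 replicate 2 had an endothelial median of 1.01, against 0.74 and 0.22 at day 7. Its macrophage median was 4.25, against 4.53 and 4.19 at day 7. Day 1 replicate 3 had an adipocyte median of 0.24, against 0.084 and -0.48 at day 7. All 11 fibroblast markers were higher by a median of 1.29 (camera adjusted p = 4.62e-05, adjusted p = 0.547 with an estimated correlation), 1 of them when adjusted over the list alone, and the median was 0.77 without day 7 replicate 1. Clec3b, a fibroblast marker that binds plasminogen, was at 99.2 ± 22.5 CPM (n = 2) against 23.4 ± 10.4 CPM (n = 3) at day 1. The macrophage list had a median of 0.95 with 10 of 13 higher (camera adjusted p = 0.00222, adjusted p = 0.912 with an estimated correlation). It did not pass without day 1 replicate 1, whose macrophage transcripts were scarce (median 0.37, camera adjusted p = 0.0655), and had a median of 1.97 without day 1 replicate 2 (adjusted p over the alternatives 1.12e-05 to 0.0655). Cd163, the haemoglobin scavenger receptor of macrophages, was at 56.0 and 26 CPM at day 7 against 0.833, 7.0 and 2.80 at day 1. The endothelial list had a median of 0.49 with 9 of 14 higher (camera adjusted p = 0.00874, adjusted p = 0.912 with an estimated correlation). Its median was 0.13 without day 1 replicate 1 (camera adjusted p = 0.161), 0.29 without replicate 3 (0.0622), 0.39 without day 7 replicate 1 (0.0516) and 1.88 without day 1 replicate 2 (1.07e-08). The skeletal muscle list had a median of 2.85 with 13 of 13 higher (camera adjusted p = 0.000178, adjusted p = 0.672 with an estimated correlation), but 0.30 without day 7 replicate 1 (camera adjusted p = 0.0775). Myh1, a fast skeletal myosin, had 52.1 CPM in that library and 1.46 in day 7 replicate 2. Of 11 adipocyte markers 5 were tested, and Adipoq, Plin1 and Lep were among those that did not pass the count filter. With 4 of the 5 higher, the adipocyte list had a median of 0.90 (camera adjusted p = 0.0452, adjusted p = 0.547 with an estimated correlation). It did not pass without day 7 replicate 1 (0.257) or with upper-quartile factors (0.0533), and its median was 1.45 without day 1 replicate 2 and 1.36 without day 7 replicate 2.

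Smooth muscle markers did not pass between the time points (median 0.20, camera adjusted p = 0.145), with a log2 fold change of Acta2 of -0.18 (SE 0.81). The smooth muscle median without day 1 replicate 1 was 0.95 (camera adjusted p = 8.76e-07). Immediate early genes did not pass either (median -0.04, camera adjusted p = 0.997). When day 7 replicate 1 was left out they passed as lower (median -0.88, camera adjusted p = 0.000719), and without day 7 replicate 2 as higher (median 0.59, camera adjusted p = 0.00462). Other lists also passed with camera between the times only when 1 library was left out. Lower at day 7 without day 1 replicate 1 were interferon response (median -0.62, camera adjusted p = 0.0140), coagulation and fibrinolysis (-1.02, adjusted p = 0.0124) and oxidative stress genes (-0.71, adjusted p = 0.0140). Lower without day 7 replicate 1 were oxidative stress (-0.82, camera adjusted p = 0.000719), hypoxia and glycolysis (-0.61, adjusted p = 0.00195) and coagulation and fibrinolysis genes (-0.74, adjusted p = 0.0417). Higher at day 7 were T and NK cell markers without day 1 replicate 2 (1.03, camera adjusted p = 0.0213) or 3 (1.15, adjusted p = 0.0217), lipid-laden phagocyte genes without day 1 replicate 2 (1.01, adjusted p = 0.00323) and Schwann cell and nerve markers without day 7 replicate 2 (0.65, adjusted p = 0.0380).

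Of the fixed genes, the log2 fold change from day 1 to day 7 was -2.48 (SE 0.88) for Ccl2, -2.58 (SE 1.48) for Il1b, -0.99 (SE 0.31) for Plat and -0.84 (SE 0.36) for Mki67. It was 1.53 (SE 0.96) for Pecam1, 0.39 (SE 1.57) for Cd68, 0.36 (SE 0.68) for Hmox1, 0.07 (SE 0.50) for Col1a1, -0.26 (SE 1.73) for Mmp9 and -0.39 (SE 0.77) for Spp1. None of these passed with edgeR.

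Between the time points edgeR called 0 of 15860 genes, limma-voom 0 and DESeq2 505 (209 higher at day 7, 296 lower), a test that called 110 unchanged genes in the simulation of this comparison. edgeR had 1602 genes at an unadjusted p under 0.05 (741 higher, 861 lower), where 793 were to be expected by chance, and the smallest adjusted p was that of Smad6 (edgeR adjusted p = 0.260, over 20 alternatives from 8.21e-27 with DESeq2 to 1 without day 7 replicate 1). Leaving out day 1 replicate 1, edgeR again called 0 and had 2042 genes at an unadjusted p under 0.05. The groups did not overlap for 5259 genes (33.2%, with 20% by chance).

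**Figure D3:**
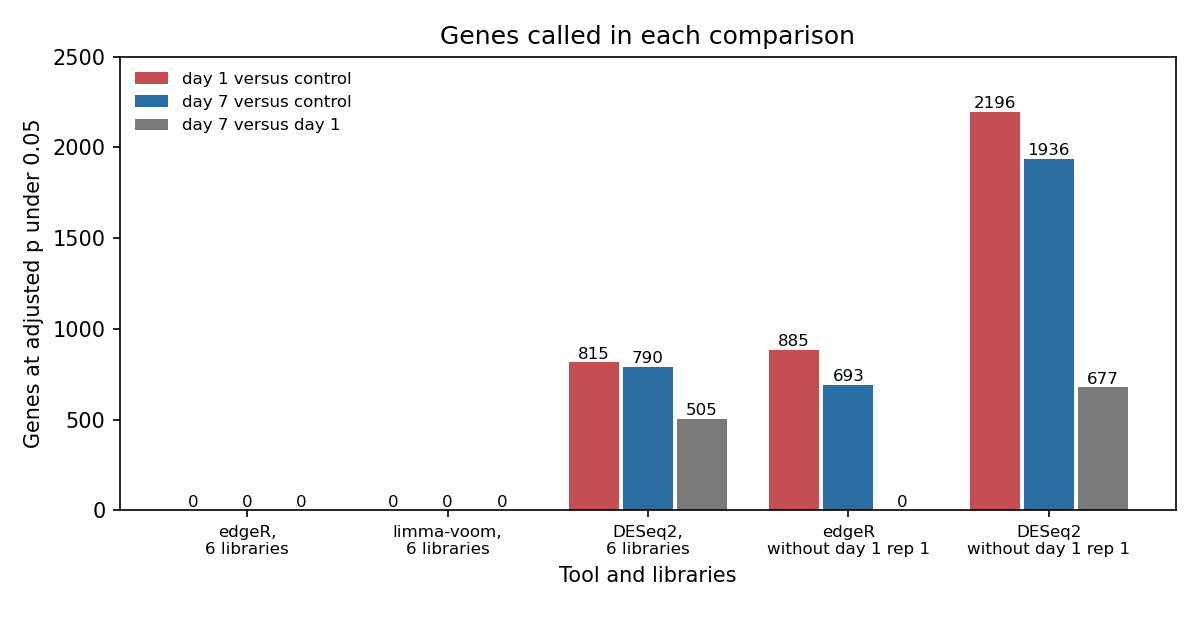
Number of genes at an adjusted p under 0.05 in the 3 comparisons with 3 tools on 6 libraries and with edgeR and DESeq2 without day 1 replicate 1. edgeR called 0, 0 and 0 genes with all libraries and 885, 693 and 0 without day 1 replicate 1, for day 1 against the control, day 7 against the control and day 7 against day 1.

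Changes against the control were compared between day 1 and day 7. The log2 fold changes had a correlation of 0.777 across 15860 genes. In 30 simulations of unchanged groups set against 1 shared control the correlation was 0.708 on average (0.697 to 0.718), since both comparisons use the same control library, which cannot be split. The sign was the same for 75.7% of genes, inside the range of the simulations (75.1% on average, 74.3 to 76.0%). At an unadjusted p under 0.05 in both comparisons, 498 genes were higher (222 on average in the simulations, and 59.5 for independent lists) and 151 were lower (74.4 and 15.9). The covariance was 1.46 against 0.625 in the simulations. Part of the excess over independent lists may come from the shared control.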

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

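The tests of day 1 replicate 1 and of blood transcripts were chosen only after the result was seen, whereas the test of further skeletal muscle genes was fixed before their values were looked at. In the camera test of day 7 against day 1 already given, in which the control cancels, 10 lists passed with the preset correlation and 0 with an estimated one. Median log2 differences were -3.01 for platelet, -2.94 for erythroid, -2.53 for inflammatory, -2.51 for neutrophil and -0.93 for cell cycle genes. They were 2.85 for skeletal muscle, 1.29 for fibroblast, 0.95 for macrophage, 0.90 for adipocyte and 0.49 for endothelial genes.

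For 18 of 122 named genes, all day 1 libraries lay on one side of the control and both day 7 libraries on the other, a difference that was not tested in this form. Many of the 122 had been named for a small p between the times, some also for no overlap between them. Their share with this pattern is therefore no evidence. The log2 difference of day 7 from day 1 was 7.06 for Sox10, 3.53 for Cd163, 2.77 for Vwf, 2.76 for Scara5, 2.73 for Ntn4, 2.44 for Smad6, 2.08 for Clec3b, 1.83 for Des, 1.83 for Ddit4, 1.79 for Smad7 and 1.67 for Id1. It was -4.68 for Mmp8, -4.55 for Gp9, -3.54 for Hba-a1, -3.54 for Nrgn, -2.11 for Stx11, -1.47 for Slc39a14 and -1.35 for Adamts1. None of them passed between day 7 and day 1 with edgeR. Among all 15860 tested genes, which are not independent replicates, 890 had this pattern, a larger share than the 3.33% that chance gives. The pattern needs day 1 and day 7 not to overlap, which held for 5259 genes (33.2%, with 20% by chance). The larger share may therefore only restate that separation and is no evidence about the place of the control. Smad6, Smad7, Id1, Ddit4, Scara5, Ntn4, Stx11 and Nrgn were chosen after their values were seen.

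Day 1 replicate 1 lacked the macrophage transcripts of the other day 1 libraries. An untreated artery under a day 1 label is argued against by a median log2 ratio of 2.94 over the control for cell cycle genes, with 18 of 18 above it (smallest 0.38). Dilution of all vessel wall transcripts by leukocytes in the other day 1 libraries is argued against by endothelial genes, which were lower in replicate 1 (median -2.04), as were fibroblast genes (-0.92), while smooth muscle genes were higher (1.56). Lower depth is argued against as well, since replicate 1 had more counts (36076387) than replicates 2 and 3 (31188546 and 30078022). After thinning to one total, 1388 genes were over 4-fold lower in replicate 1 than in both others, without normalization factors. Without thinning there were 1241, with normalization factors, so these counts differ in scaling too. Whether the library carries the right label stays open, because no other mislabelling (an artery of another time or from outside the series) was tested, and no biological explanation was tested, since all 3 libraries carry the same group label.

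Skeletal muscle transcripts were highest in day 7 replicate 1 for 11 of 13 list members. Muscle fibres in the dissected piece are a candidate source, and 6 of 10 further skeletal muscle genes had their highest CPM there, where 8 had been set as needed and 3 or fewer as evidence against it. This leaves the source open. Ckm, an abundant muscle transcript, had 20.4 CPM there and 40.2 CPM in the control. No biological explanation was tested.

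Erythroid transcripts were highest at day 1. Blood as the source of the macrophage transcripts at day 7 is argued against, if it had the composition of the control's, since their median exceeded the haemoglobin log2 ratio over the control by 3.41 and 6.58, with haemoglobin in replicate 2 below the control (151 against 791 CPM). For day 1 blood stays open as the source: the library with the most haemoglobin had a macrophage median 5.10 log2 units below the lowest of the other 4 treated libraries, but this is 1 library, and of the other 2 day 1 libraries the one with more haemoglobin had the higher median (4.25 against 3.55). The gap between macrophage median and haemoglobin ratio, used for day 7, was -4.69, 1.92 and 1.45 in day 1 replicates 1 to 3. In replicates 2 and 3, 12 and 8 of 13 markers lay above the haemoglobin ratio, and in replicate 1 0 did. More blood at day 1 than in the control stays open, since the erythroid median exceeded the platelet median by 0.73 to 3.31 log2 units in the day 1 libraries, and only a gap over 1 in each would have argued against it. Time after recanalization, which the design gives, stays open as untested.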

How the results depend on the processing

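DESeq2 without day 1 replicate 1 was chosen after seeing the data; the other alternatives were planned. Of the counts of genes past the threshold, all 0 with edgeR on 6 libraries, 39 stayed alike and 14 moved. DESeq2 called 505 genes (day 7 against day 1), 815 (day 1 against the control) and 790 (day 7 against the control), and without day 1 replicate 1 677, 2196 and 1936. With 1 library left out, edgeR counts ranged from 0 to 885 for day 1 against the control, from 0 to 693 for day 7 against the control, and stayed at 0 between the times, each highest value being without day 1 replicate 1. Without a low-count filter 1 gene passed for day 7 against the control. limma-trend on log2(FPKM + 1) called 1 gene for day 1 and 2 for day 7 against the control, and on log2(FPKM + 0.1) 1 and 1. With FPKM + 0.1 the median of all genes shifted by 0.15 between the times and by 0.19 for day 7 against the control, and with FPKM + 1 by 0.12 for the latter. The correlation of same-numbered deviations was -0.056 by title and 0.051 by description. With 2 pairs the other pairing gives the same value with the opposite sign, so these values leave open whether the samples are paired. The replicate block by description numbers called 134 genes (0 without the block on the same 4 libraries), by title numbers 0. The overlap against the shared control was 649 genes, 636 with median-of-ratios and 648 with upper-quartile factors.

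With an estimated correlation 0, 0 and 0 lists passed in place of 10, 17 and 16 (day 7 against day 1, day 1 and day 7 against the control), by directional fry 1, 2 and 0, and by mixed fry 8, 5 and 2. Between the times, directional fry passed Schwann cell and nerve markers (fry adjusted p = 0.0486), which camera did not pass. It passed none of the 10 camera lists (fry adjusted p at least 0.213). Mixed fry, which ignores direction, passed the inflammatory, neutrophil, platelet and cell cycle lists among others. Over all alternatives 659 list results stayed alike, 148 became weaker, 26 stronger and 37 had the opposite direction of the test, of which 1 passed, immediate early genes between the times (0.59 without day 7 replicate 2). Single genes, of which edgeR on 6 libraries called none, kept their side of the threshold in 5428 results, passed newly in 572 and had the opposite sign in 44. Among the reversed results, Acta2 between the times passed with DESeq2 without day 1 replicate 1 (0.93, DESeq2 adjusted p = 0.0179). Log2 values between day 7 and day 1 that reversed were these. With 1 library left out they ranged from -0.54 (without day 1 replicate 2) to 0.95 (without day 1 replicate 1) for Acta2, -0.19 (day 1 replicate 1) to 1.31 (day 1 replicate 2) for Cd68, -0.49 (day 7 replicate 2) to 0.47 (day 7 replicate 1) for Col1a1, -3.0 (day 7 replicate 1) to 0.81 (day 1 replicate 2) for Mmp9, -0.031 (day 1 replicate 1) to 1.19 (day 1 replicate 2) for Hmox1, -0.72 (day 1 replicate 1) to 0.058 (day 1 replicate 3) for Tg and -2.81 (day 7 replicate 2) to 1.05 (day 1 replicate 2) for Epcam. For genes lowest without day 7 replicate 1 the range was -0.031 to 0.50 for Cox4i1, -0.27 to 1.01 for Cd36, -1.32 to 2.43 for Nr4a1, -0.19 to 1.35 for Klf2 and -0.115 to 0.97 for Ier2, and for the immediate early list -0.88 to 0.59. Cd68 also reversed without day 7 replicate 1 (-0.08), Col1a1 without day 1 replicate 1 (-0.062) and Mmp9 without day 7 replicate 2 (0.62). DESeq2 without day 1 replicate 1 gave 0.93 for Acta2, -0.22 for Cd68, -0.087 for Col1a1, -0.067 for Hmox1 and -0.0023 for Pax8. The block by description numbers gave 0.95 for Acta2, -0.18 for Cd68 and -0.14 for Col1a1, and the same 4 libraries without the block 0.96, -0.19, -0.059 and, for Hmox1, -0.031. The block by title numbers gave 0.39 for Spp1, 1.05 for Mmp9 and 0.17 for Tg, and the libraries without it 0.056 for Tg. limma-voom gave 0.22 for Acta2 and 0.53 for Mmp9, FPKM + 1 gave 0.33 for Acta2, 0.091 for Spp1 and 0.013 for Mmp9, and FPKM + 0.1 gave 0.335, 0.091 and 0.39. For day 7 against the control the range with 1 library left out was -0.56 (day 7 replicate 1) to 0.041 (day 7 replicate 2) for Pecam1, -0.87 (day 7 replicate 2) to 0.090 (day 7 replicate 1) for Col1a1 and -5.08 (day 7 replicate 1) to 1.66 (day 7 replicate 2) for Ahsp, which was at -0.59 by limma-voom and -0.11 with FPKM + 0.1. The cause was not tested. Where only 1 day 7 library is left, it is assumed to vary like the other groups.

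The direction of a list test can differ from the sign of its median. Medians of the other lists whose direction reversed, none of them past the threshold where it reversed, ranged as follows with 1 library left out. Between day 7 and day 1 they were -0.17 to 0.95 for smooth muscle, -1.14 to 1.47 for B cell, -0.72 to 0.058 for thyroid, -1.38 to 0.94 for interferon, -0.76 to 0.15 for fibrillar matrix, -1.79 to 0.81 for matrix protease, -0.61 to -0.17 for hypoxia, -0.062 to 0.45 for iron handling, -0.099 to 0.15 for heat shock, -0.17 to 0.14 for mitochondrial respiration and -0.077 to 1.01 for lipid-laden phagocyte genes. For day 1 against the control they were -1.07 to 0.74 for endothelial and 0.16 to 1.51 for interferon genes, and for day 7 against the control -2.72 to 0.99 for erythroid, -0.48 to 0.084 for adipocyte, -0.089 to 1.26 for interferon and -0.24 to -0.057 for mitochondrial respiration genes. Upper-quartile factors reversed matrix protease (-0.21), heat shock (0.13) and mitochondrial respiration genes (0.082) between the times, and directional fry heat shock (0.079), mitochondrial respiration (0.029) and immediate early genes (-0.040).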

Other observations

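Tests of BMP and NF-kB target genes were written before their values were looked at, and no test in this part was chosen only after the result was seen. The genes of the next 2 paragraphs were chosen after their values were seen. The following 6 genes of class II antigen presentation were picked one by one, and no list of them was fixed or tested. Cd74, the invariant chain of class II molecules, had 0.292 CPM in the control, 4.32, 315 and 147 CPM in day 1 replicates 1 to 3 and 1132 and 727 CPM at day 7. RT1-Da, a rat class II alpha chain, had 0 counts in the control, 1.19, 124 and 72.4 CPM at day 1 and 347 and 262 CPM at day 7, and RT1-Ba had 0.0325, then 0.0640, 33.4 and 11.4, then 73.9 and 62.6 CPM. Ciita, the transcriptional activator of class II genes, had 0.260 CPM in the control, 0.897, 7.28 and 5.28 CPM at day 1 and 18.8 and 14 CPM at day 7. RT1-DMb, a chain of the peptide exchange factor, had 0.584 CPM in the control, 0.0640, 0.802 and 0.290 CPM at day 1 and 25.4 and 13.6 CPM at day 7. RT1-DMa, its other chain, had 0.487 CPM in the control, 0.320, 1.57 and 0.773 CPM at day 1 and 1.76 and 1.46 CPM at day 7. RT1 genes belong to a multigene family, and their levels are given as uncertain because it was not tested whether reads were split between its members. For day 7 against the control the edgeR adjusted p was 0.477 for Cd74, RT1-Da, RT1-Ba, RT1-DMb and Ciita, and 0.550 for RT1-DMa.

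Sost, an inhibitor of Wnt signalling made by osteocytes and by some arterial cells, had 0.0649 CPM in the control (2 counts), 0.0961, 0.0617 and 0.0966 CPM at day 1 and 16.4 and 68.2 CPM at day 7. Comp, cartilage oligomeric matrix protein, had 6.85 CPM in the control, 3.91, 15.6 and 16.8 CPM at day 1 and 198 and 310 CPM at day 7. Alpl, the alkaline phosphatase that enables mineralization, was lower, with 160 CPM in the control, 31.5, 29.0 and 56.4 CPM at day 1 and 12.3 and 13 CPM at day 7. The edgeR adjusted p for day 7 against day 1 was 0.402 for Sost and Comp and 0.420 for Alpl. Over 20 alternatives it ranged from 1.42e-19 to 0.782 for Sost, from 4.55e-26 to 1 for Comp and from 0.000581 to 1 for Alpl.

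It was hypothesized that BMP target genes may be higher at day 7 than at day 1, after Smad6, Smad7 and Id1 had been seen to be. In 10 other target genes the median log2 fold change was 0.83, with 6 higher and 4 lower (camera p = 0.0295 with the preset correlation and p = 0.327 with an estimated correlation), and 2 were called when adjusted over the list alone. Atoh8, a transcription factor induced by BMP9 in endothelium, had 39.2 and 36.7 CPM at day 7 against 11.1, 3.61 and 7.44 at day 1, and Id2, an inhibitor of basic helix-loop-helix factors, 88.1 and 137 CPM against 40.1, 47.0 and 33.8. The test leaves the hypothesis open.

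It was also hypothesized that NF-kB target genes may be lower at day 7, after Relb and Birc3 had been seen to be. In 12 other target genes the median log2 fold change was -0.31, with 10 lower and 2 higher (camera p = 0.0427 with the preset correlation and p = 0.501 with an estimated correlation), and 0 were called when adjusted over the list alone (3 at an unadjusted p under 0.05). Nfkb2, a subunit precursor of NF-kB, had 67.0 and 56.5 CPM at day 7 against 94.7, 145 and 102 at day 1. The test leaves this hypothesis open as well.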
